A study of Mus musculus with 2 samples.

How the data were processed

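The deposited values were raw UMI counts per gene and barcode from 10x 3' gene expression libraries, with 1 library of control and 1 of basophil-depleted mice. Per the submitters' processing notes, the authors used Cell Ranger 3.1.0, bcl2fastq 2.20.0.422 and the mouse build mm10. The annotation release and the steps between these tools are not given in the sources used here. The count matrices list every barcode of the 10x list, so the deposited counts had passed no cell calling. Per the labels, sorted cells of 6 mice per group were pooled into 2 samples per group, 10000 cells were sorted and purity was at least 98%. The sex of the mice is not given in the labels. Gene positions were taken from GENCODE vM21, which is built on mm10, by Ensembl identifier, with 30934 identifiers matched.

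Cells were called per library as barcodes whose UMI total reached the 99 percentile of the 3000 barcodes with most UMIs divided by 10, with at least 200 genes and at most 10% of UMIs from mitochondrial genes. The UMI minimum was 4370.5 in the control library, where 3620 barcodes with 78.7% of UMIs passed, and 5607.56 in the basophil-depleted library, where 4671 barcodes with 78.8% of UMIs passed. Of the control cells, 349 lay under the minimum of the other library. The mitochondrial filter removed 57 and 71 barcodes. Scrublet (scanpy 1.11.5, expected rate 5%) marked 3 control cells (0.0842%) and 0 basophil-depleted cells as doublets. At that rate the caller has not worked, and the marked cells were removed. Both libraries were clustered together without integration (normalization to 10000, log1p, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, seeded, igraph 0.11.9). Fixed markers of 15 cell types were scored in each cluster, but the naming rule gave only the names ILC2-like, T cell-like and NK or ILC1-like. Other clusters were left unnamed, so no cluster could be named ILC3-like. Clusters with at least 0.5 of the median summed CPM of Il1rl1, Klrg1 and Arg1 over clusters were called ILC2-like, a threshold set after the data were seen.

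Counts of ILC2-like cells were summed per library to 36097231 and 60336947 UMIs and scaled to CPM, UMIs relative to the library's sum. Log2 ratios used a prior of 1 CPM. Intervals are 95% exact Poisson intervals for CPM, exact conditional binomial intervals for ratios and exact binomial (Clopper-Pearson) intervals for shares. Genes with 0 counts were given a floor of 3 counts. The size rule asked for at least 20 CPM in the higher library and at least 1.5-fold. With 1 sample per group no test was run, and the counts of higher and lower genes describe these libraries. The median log2 ratio of each of 21 gene lists was taken over members at 5 CPM or more in either library and given as a percentile among 10000 random lists of the same size, matched in 20 expression bins. Shares of cells with a UMI and of cycling cells (at least 3 of 17 mitotic genes) were taken after thinning each cell to 2000 UMIs. Named genes were the 12 with the largest and the 12 with the smallest log2 ratio, up to 4 members of each list with the largest ratios at 20 CPM or more, and a fixed set with Nmbr, Nmur1, Il4, Il5, Il13, Areg, Gata3, Il1rl1, Il7r, Klrg1, Mki67 and the sex chromosome genes. Unnamed gene models and ribosomal, mitochondrial, globin and immunoglobulin genes were left out of the first part.

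Cells were called female-typed with 3 or more Xist or Tsix UMIs and no UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, and male-typed with no Xist or Tsix UMI. This typing was added after the control library was seen to hold almost no Y-linked UMIs. The design, the lists, the named-gene rule and most alternatives were fixed before the data were examined. Alternatives were other scalings (edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors), sets and weights of cells, UMI minimums of 1000 and 3000, the mitochondrial and doublet filters, removal of free RNA, other priors, minimums, thinning depths and clustering resolutions. The size rule and the intervals were tested on simulated Poisson counts for the comparison of ILC2-like cells, drawn from the real means and library sizes with 200 genes at known folds. All genes set to 2-fold or 3-fold were recovered (100% in each direction), 0% of genes set to 1.25-fold passed, and the 95% intervals covered the set ratio for 94.7% of genes at 20 CPM or more. The intervals are built for Poisson counts, so these outcomes check the computation only. The draws held no spread between cells, mice or pools and no mix of sexes. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.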

Results

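Lung group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes that release type 2 cytokines without using an antigen receptor. They were compared by single-cell RNA sequencing between control mice and mice labelled basophil-depleted. All mice had been infected 5 days earlier with Nippostrongylus brasiliensis, a rodent hookworm whose larvae pass through the lung. The series title places the question in how basophils prepare ILC2s for inhibition by neuropeptides. Live CD45+ cells were sorted that lacked lineage markers and FceR1, the IgE receptor of basophils and mast cells, and that carried CD90 and CD127. Per the labels, cells of 6 mice per group were pooled into 2 samples per group. A single sample of each group was analysed here, named control (wildtype) and basophil-depleted. The control library held 51943873 UMIs and the basophil-depleted library 81718021. After filtering, 3560 control cells with a median of 9008.5 UMIs and 4600 basophil-depleted cells with a median of 10881.5 UMIs remained. With 1 sample per group no test could be run, no difference below has a replicate check, and every interval is a 95% interval that covers counting error only.

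Most sorted cells of both libraries were ILC2-like. They made up 83.6% of control cells (2975 cells, exact binomial interval 82.3 to 84.8%) and 91.1% of basophil-depleted cells (4189 cells, 90.2 to 91.9%). NK or ILC1-like cells made up 2.53% (2.04 to 3.1%) and 2.15% (1.75 to 2.61%), and T cell-like cells 4.19% (3.55 to 4.90%) and 4.11% (3.55 to 4.72%). The remaining difference lay in an unnamed cluster led by Ccr10, Jaml, Cd7, Ccr6 and Ccl5, which held 9.72% of control cells (8.77 to 10.7%) and 2.67% of basophil-depleted cells (2.23 to 3.18%). Its cells carried Gata3, the lineage-defining factor of ILC2s, at 308 CPM in the control library and 287 CPM in the basophil-depleted library, and Il1rl1, the IL-33 receptor, at 65.1 and 124.9 CPM. T cell-like cells held Gata3 at 231 and 214 CPM and Il1rl1 at 109 and 122 CPM. NK or ILC1-like cells held Gata3 at 194 and 204.5 CPM and Il1rl1 at 94.9 and 91.1 CPM. Gata3 and Il1rl1 therefore do not settle whether the unnamed cluster holds ILC2s. Cd3d stood at 7.71 and 12.7 CPM in that cluster, against 813 and 777 CPM in T cell-like cells. Ncr1 stood at 0 and 1.06 CPM, against 263 and 232 CPM in NK or ILC1-like cells. Ccl5, at 1789 and 1086 CPM, was high as in those classes. A threshold on the summed CPM of Il1rl1, Klrg1 and Arg1, set after the data were seen, kept the unnamed cluster out of the ILC2-like class. The UMI minimum for cells was 4370.5 in the control library and 5607.56 in the basophil-depleted library. With 1 minimum for both, the cluster held 12.6 and 3.8% of cells at 1000 UMIs, and 12.8 and 4.89% at 3000. The sort gate can also set these shares. The doublet caller has not worked here, since it marked 3 control cells (0.0842%) and 0 basophil-depleted cells.

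**Figure D1:**
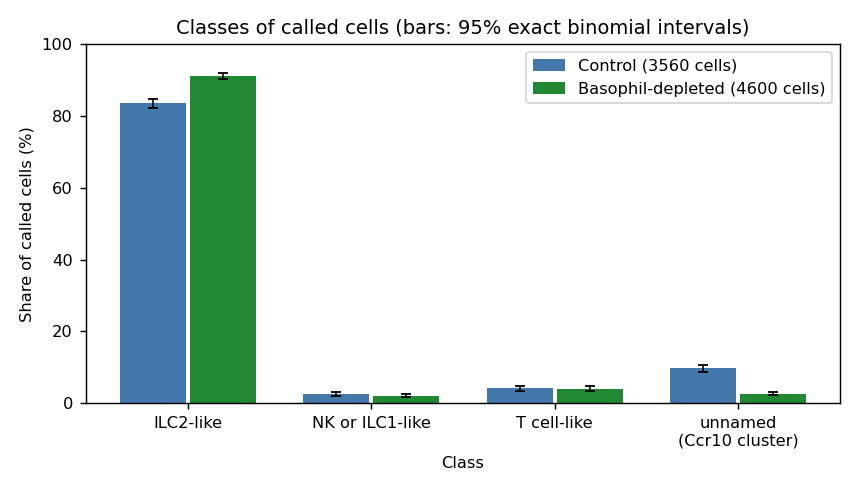
Share of called cells (%) in each class, for the control library (3560 cells) and the basophil-depleted library (4600 cells), with bars for 95% exact binomial intervals. The ILC2-like share was 83.6% against 91.1%, and the unnamed cluster led by Ccr10 held 9.72% against 2.67%.

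The sex of the cells differed between the libraries. Xist, the RNA that silences an X chromosome in female cells, stood at 1274 CPM in control ILC2-like cells and at 228 CPM in basophil-depleted ones. The Y-linked genes Eif2s3y and Ddx3y had 0 UMIs in control ILC2-like cells, where the floor of 3 UMIs is 0.0831 CPM, and 67.9 and 60.5 CPM in basophil-depleted cells. Kdm5d stood at 0.139 and 9.02 CPM, Uty at 0.0831 and 17.0 CPM, and Tsix, the antisense partner of Xist, at 70.3 and 11.5 CPM. Of the 6 sex chromosome genes, Xist and Tsix were lower and Eif2s3y and Ddx3y higher in the basophil-depleted library by the size rule, and the list median was 3.60 on the log2 scale with the prior of 1 CPM and 6.85 without it, with counts of 0 at their floor. Of control ILC2-like cells, 97.6% (97.0 to 98.2%) were female-typed, with 3 or more Xist or Tsix UMIs and no Y-linked UMI. Of basophil-depleted ILC2-like cells, 18.6% (779 cells, 17.4 to 19.8%) were female-typed and 76.1% (3189 cells, 74.8 to 77.4%) were male-typed, with no Xist or Tsix UMI. Gene counts, list medians, the ratios of many named genes and the main shares are therefore also given for female-typed cells alone, an alternative added after the data were seen. The typing left out 105 basophil-depleted and 8 control ILC2-like cells that had 3 or more Xist or Tsix UMIs and also a Y-linked UMI. In all, 221 basophil-depleted and 59 control ILC2-like cells were neither female-typed nor male-typed. Of 498 basophil-depleted ILC2-like cells that were cycling after thinning, 47 were female-typed and 403 male-typed. The untyped cells there were thus cycling more often than either typed class, so the typing removed cycling cells unevenly. Whether the loss fell more on deeper cells was not tested.

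Among ILC2-like cells, Il13, Il5 and Calca were higher and Il2 and Lgals3 lower in the basophil-depleted library, and for Il13 and Il5 the difference lay mostly in its male-typed cells. Il13, a cytokine that drives mucus production and worm expulsion, stood at 271 CPM in control cells and 504 CPM in basophil-depleted cells, 1.86-fold higher (1.82 to 1.90). Il5, which sustains eosinophils, stood at 111 and 189.8 CPM, 1.71-fold higher (1.65 to 1.77), and Calca, the gene of the neuropeptide CGRP, at 107 and 194 CPM, 1.81-fold higher (1.74 to 1.88). Il2 went the other way, from 52.1 CPM in control cells to 24.3 CPM, 2.14-fold lower in the basophil-depleted library (2.00 to 2.29), and Lgals3, the gene of galectin-3, was 1.74-fold lower (1.70 to 1.77). In mm10, Il13 (ENSMUSG00000020383) lies on chromosome 11 from 53631324 to 53634702, Il5 (ENSMUSG00000036117) on chromosome 11 from 53720794 to 53725106, and Il2 (ENSMUSG00000027720) on chromosome 3 from 37120523 to 37125959. In female-typed cells the ratio of basophil-depleted to control was 0.960 for Il13 (0.918 to 1.003), 1.10 for Il5 (1.03 to 1.18) and 1.40 for Calca (1.32 to 1.49).

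By the size rule, at least 20 CPM in the higher library and at least 1.5-fold, 67 of 5143 genes were higher and 58 were lower in basophil-depleted ILC2-like cells. That is 53.6% higher, against 67.6% (94 higher, 45 lower) with edgeR's TMM factors and 70.8% (97 higher, 40 lower) with DESeq2's size factors. In female-typed cells 10 genes were higher and 44 lower, and of the 125 genes past the rule over all cells, 5 higher and 12 lower genes were also past it there. The 65 higher genes outside the sex chromosome list had a median log2 ratio of 0.68 over all cells and 0.20 in female-typed cells. The 56 lower genes had medians of -0.68 and -0.34. Within the basophil-depleted library, male-typed cells had 141 genes higher and 63 lower than female-typed cells, and 36 of the 67 higher genes and 19 of the 58 lower genes were past the rule in the same direction there. Different clusters held most of the class in each library: clusters 5, 4, 6 and 7 among control cells, and clusters 9, 11, 2 and 1 among basophil-depleted cells. Among basophil-depleted cells, clusters 9, 2 and 1 held 957, 691 and 552 male-typed cells and 15, 19 and 26 female-typed cells. Clusters 5, 4 and 6 held 18, 22 and 12 male-typed and 268, 157 and 82 female-typed cells. The split between these clusters went with the sex of the cells, so it cannot be read as a shift with basophil depletion. Sex chromosome genes were not left out of the clustering. Eif2s3y was among the top 10 genes of cluster 2, Ddx3y of cluster 9, and Xist and Tsix of clusters 5 and 6. These genes may themselves bring part of the split, so it need not be one of cell state.

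Outside the sex chromosome list, the genes with the largest ratios over all ILC2-like cells were Tmem86a at 2.99-fold (2.62 to 3.42), Gda, a guanine deaminase, at 2.95-fold (2.60 to 3.35), the chemokine receptor Ccr5 at 2.11-fold (1.89 to 2.37), Gadd45g at 2.05-fold (1.90 to 2.21) and Stc2 at 1.96-fold (1.76 to 2.19). Dgat2, an enzyme of triglyceride synthesis, was 1.86-fold higher, the stress gene Ier3 1.87-fold and Rrm2, a subunit of ribonucleotide reductase, 1.79-fold. In female-typed cells these ratios were 1.18 for Tmem86a, 1.57 for Gda, 1.26 for Ccr5, 1.19 for Gadd45g, 2.34 for Stc2, 0.869 for Dgat2, 0.647 for Ier3 and 0.986 for Rrm2. The lowest genes included Txnip, a glucose-responsive inhibitor of thioredoxin, at 278 CPM in control and 116 CPM in basophil-depleted cells (2.39-fold lower, 2.31 to 2.46). Zfp36l2, which binds AU-rich mRNA, was 2.00-fold lower, Tsc22d3, a glucocorticoid-induced gene, 1.99-fold, Gstp1 1.94-fold, Ccdc85b 1.95-fold, Pik3ip1 1.91-fold, Uba52 1.87-fold, St3gal6 1.81-fold and Bcl2a1b 1.78-fold. In female-typed cells Gstp1 was 2.21-fold lower, Uba52 1.79-fold, Ccdc85b 1.62-fold and Bcl2a1b 1.59-fold. There Zfp36l2 was 1.40-fold lower, St3gal6 1.32-fold, Tsc22d3 1.18-fold and Txnip 1.14-fold, and Pik3ip1 was at a ratio of 1.09. Counts of Uba52, Gstp1 and Bcl2a1b are uncertain, since near-identical copies (Gm11808, Gstp2 and Bcl2a1d) share their sequence, and reads of Xist and Tsix overlap on opposite strands.

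**Figure D2:**
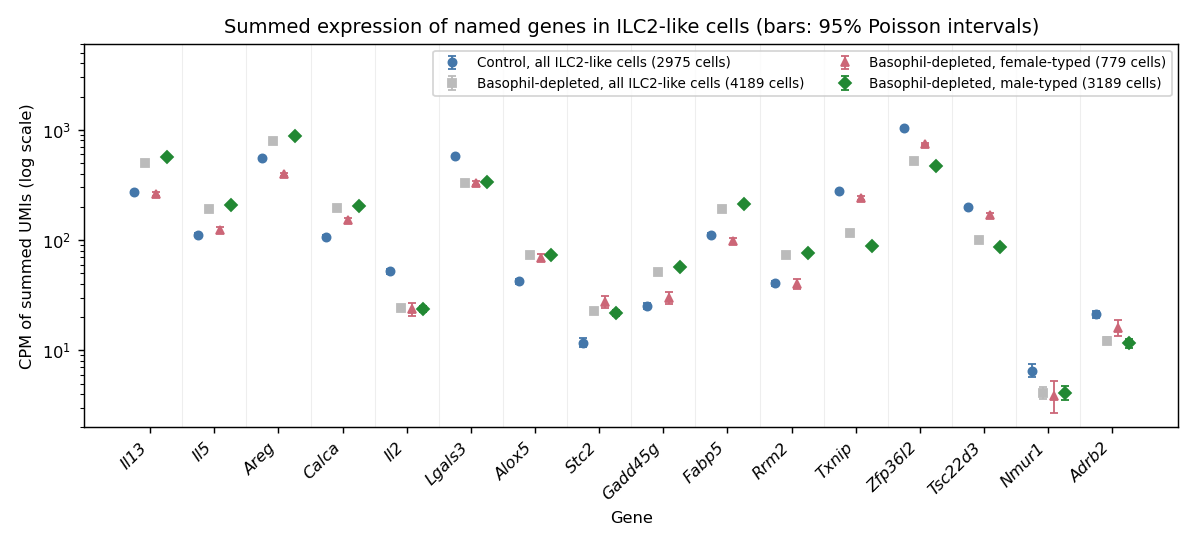
Summed expression (CPM, log scale) of 16 named genes in control ILC2-like cells (2975 cells), all basophil-depleted ILC2-like cells (4189), and the female-typed (779) and male-typed (3189) cells among the latter, with bars for 95% Poisson intervals. For Il13, basophil-depleted female-typed cells (262 CPM) sit near control cells (271 CPM) and male-typed cells (568 CPM) above them, while for Il2 both basophil-depleted classes (23.5 and 23.7 CPM) sit below control cells (52.1 CPM).

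Secreted effectors as a list had a median log2 ratio of 0.16 over 22 measured genes, at the 98.3 percentile of 10000 random lists matched on expression. Of 20 genes at 20 CPM or more, 4 were higher, 4 lower and 12 within the size rule. Areg, the epithelial repair factor amphiregulin, was within it at 551 and 783 CPM, and Il4 at 22.4 and 24.9 CPM. In female-typed cells the list median was -0.32 at the 0 percentile, with 0 genes higher and 4 lower, and Areg stood at 554 CPM in control and 396 CPM in basophil-depleted cells. After thinning each cell to 2000 UMIs, Il13 was detected in 15.6% of control ILC2-like cells (14.3 to 17.0%) and 26.2% of basophil-depleted ones (24.9 to 27.5%). Il5 was detected in 11.4% (10.3 to 12.6%) and 19.8% (18.6 to 21.03%), and Areg in 35.0% (33.2 to 36.7%) and 47.5% (46.0 to 49.1%). In female-typed cells the shares were 15.6 and 15.9% for Il13, 11.5 and 12.2% for Il5, and 35.0 and 31.1% for Areg. In T cell-like cells, set beside these for free RNA though expression of their own was not excluded, the shares were 1.34 and 5.29% for Il13, 0 of 149 and 4.23% for Il5, and 4.70 and 4.23% for Areg. Il4 was detected in 3.70 and 4.42% of ILC2-like cells and in 4.03 and 4.76% of T cell-like cells, so its detection was no higher in the class as a whole. Cluster 7 of the ILC2-like class nevertheless held Il4 among its top 10 genes against all other cells. Median depths were 9720 and 11382 UMIs in ILC2-like cells, and 6403 and 6946 UMIs in T cell-like cells.

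**Figure D3:**
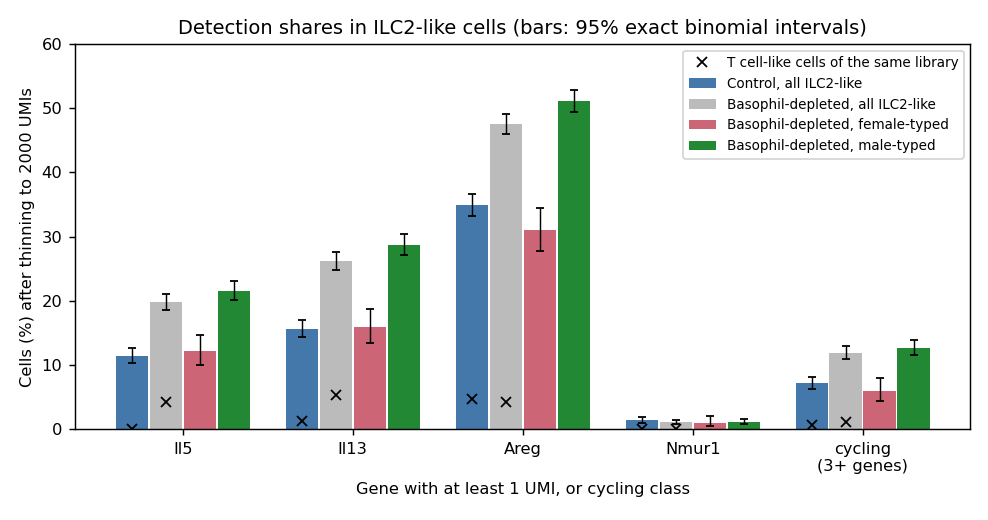
Share of ILC2-like cells (%) with at least 1 UMI of Il5, Il13, Areg or Nmur1, and of cycling cells with at least 3 of 17 mitotic genes detected, after thinning to 2000 UMIs; bars show 95% exact binomial intervals and crosses the share in T cell-like cells of the same library. For Il13 the shares were 15.6% in control cells, 26.2% in all basophil-depleted cells, 15.9% in female-typed and 28.8% in male-typed basophil-depleted cells.

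Proliferation genes were higher in the basophil-depleted library over all ILC2-like cells, while in its female-typed cells the list median and the thinned share of cycling cells were not. The list of 42 genes had a median log2 ratio of 0.50 at the 100 percentile, all 42 ratios were above 0, and 10 of 37 tested genes were past the size rule. Gins2, which helps start DNA replication, was 1.76-fold higher (1.60 to 1.95), the thymidine kinase Tk1 1.65-fold (1.52 to 1.79) and Mcm5 of the replicative helicase 1.60-fold (1.5 to 1.70). Mki67 was within the rule at 130.4 and 177 CPM. In female-typed cells the median was -0.10 at the 0 percentile, and Gins2, Tk1, Mcm5 and Mki67 had ratios of 1.10, 1.09, 1.09 and 0.827. Cycling cells made up 7.19% of control ILC2-like cells (6.29 to 8.18%) and 11.9% of basophil-depleted ones (10.9 to 12.9%) after thinning to 2000 UMIs, with 0 cells left out, and 15.97% and 28.7% without thinning. Among female-typed cells the thinned shares were 7.16% (6.25 to 8.16%) and 6.03% (4.47 to 7.94%), and without thinning they were 16.1% (14.8 to 17.5%) and 20.03% (17.3 to 23.0%), higher in the basophil-depleted library. Thinned male-typed basophil-depleted cells had 12.6% (11.5 to 13.8%). Untyped basophil-depleted cells were cycling more often than both typed classes, so the typing may lower the female-typed share and list median. T cell-like cells had 0.671% and 1.06%, and the part of free RNA in these calls stays open.

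Metabolic and stress lists were also higher over all ILC2-like cells. In female-typed cells oxidative phosphorylation stayed higher than random lists, and the others lay near 0 or below it. Amino acid metabolism and transport had a median of 0.28 over 21 genes (2 of 18 tested genes higher, Phgdh of serine synthesis at 1.60-fold and Srm of spermidine synthesis at 1.54-fold). The unfolded protein response stood at 0.25 (0 of 16 past the rule, Calr at 1.46-fold), nuclear genes of oxidative phosphorylation at 0.23 (0 of 32, Cycs at 1.41-fold), and glycolysis and hypoxia at 0.18 (1 of 18 lower, Pdk1 at 1.61-fold lower, with Ldha at 1.38-fold higher). Lipid uptake and fatty acid metabolism stood at 0.18 (2 of 16 higher, Dgat2 and the fatty acid carrier Fabp5 at 1.73-fold). These 5 medians lay at percentiles of 100, 100, 99.97, 99.6 and 99.97. In female-typed cells the medians were -0.012 for amino acids, 0.024 for the unfolded protein response, 0.10 for oxidative phosphorylation (29 of 32 ratios above 0), -0.0071 for glycolysis and -0.13 for lipids, at percentiles of 14.8, 42.0, 99.8, 14.9 and 0.01. Ribosomal protein genes had a median of -0.03 (0 of 32 past the rule, Rps27 at 1.48-fold lower), which was 0.015 with TMM factors and 0.024 with DESeq2's. Mitochondrially encoded transcripts stood at -0.02 (0 of 13), which was 0.031 with TMM factors and 0.041 with DESeq2's. Female-typed cells had medians of 0.043 for ribosomal proteins and -0.0011 for mitochondrial transcripts.

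**Figure D4:**
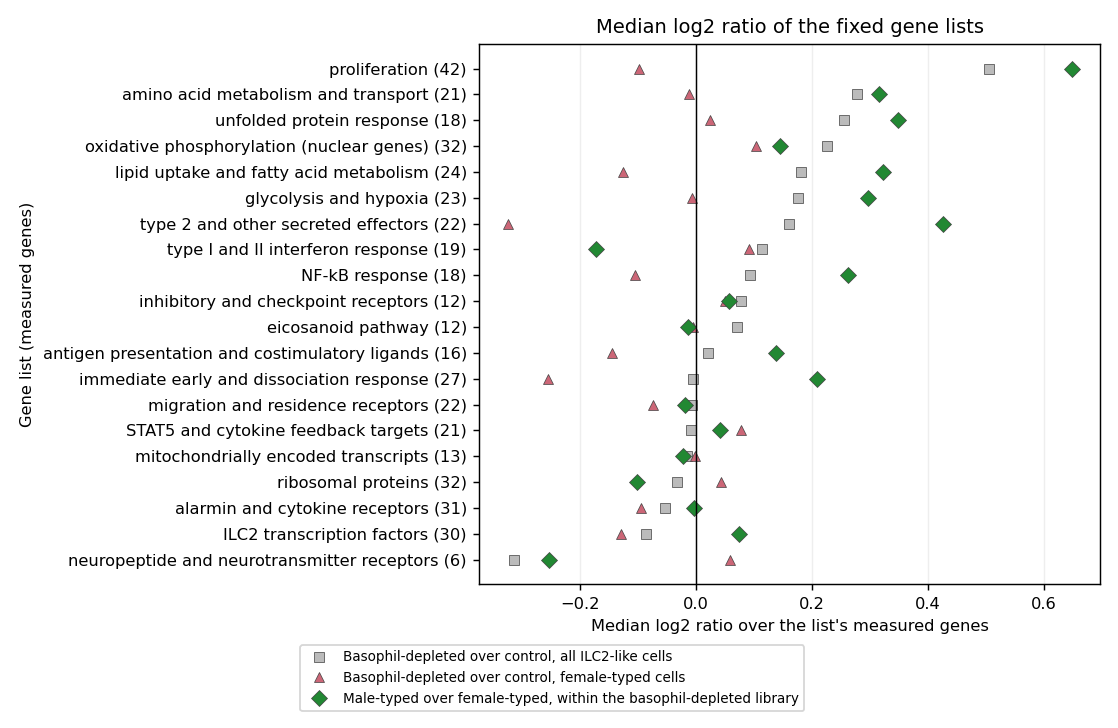
Median log2 ratio over the measured genes of 20 fixed lists (number of measured genes in brackets): basophil-depleted over control in all ILC2-like cells (squares) and in female-typed cells (triangles), and male-typed over female-typed cells within the basophil-depleted library (diamonds). Proliferation had the highest median over all cells (0.50), stood at -0.10 in female-typed cells, and at 0.65 between male-typed and female-typed cells.

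Receptor, transcription factor and activation lists had medians nearer 0 over all cells, of which transcription factors lay at the 0.17 percentile and were low against random lists. The others lay at percentiles of 3.34 (alarmin receptors), 74.0 (checkpoint), 26.5 (STAT5), 23.7 (migration), 75.3 (eicosanoids), 40.1 (antigen presentation), 79.9 (NF-kB), 97.0 (interferon) and 11.6 (immediate early). Alarmin and cytokine receptors stood at -0.05 (0 of 24 past the rule), with Il1rl1 at 486 and 489 CPM and Il7r, the IL-7 receptor, at 850.5 and 603 CPM (835 CPM in basophil-depleted female-typed cells). ILC2 transcription factors stood at -0.08 (1 of 29 lower, the repressor Bach2 at 1.55-fold), with Gata3 at 590.2 and 528 CPM and Batf at 79.9 and 109 CPM. Inhibitory and checkpoint receptors stood at 0.08 (0 of 9), with Klrg1 at 163 and 221 CPM and Pdcd1 at 83.3 and 114 CPM. STAT5 and cytokine feedback targets stood at -0.01 (2 of 16 higher, Gadd45g and Socs3, the latter at 1.61-fold). Migration and residence receptors also stood at -0.01 (2 of 16 lower, Ccr9 at 1.62-fold and Ccr8 at 1.58-fold). The eicosanoid pathway stood at 0.07 (1 of 9 higher), and its higher member Alox5, the 5-lipoxygenase of leukotriene synthesis, was 1.72-fold higher over all cells (1.62 to 1.83) and 1.65-fold in female-typed cells (1.5 to 1.80). Antigen presentation and costimulatory ligands stood at 0.02 (1 of 13 lower, Tnfsf8 at 1.65-fold), and the NF-kB response at 0.09 (0 of 17). The interferon response stood at 0.11 (1 of 10 higher), and its higher member Ifi27l2a was 1.65-fold higher over all cells and 2.48-fold in female-typed cells (2.17 to 2.84). Immediate early and dissociation genes stood at -0.01 (3 of 25 higher, 2 lower), with Fosb 1.64-fold and Zfp36 1.57-fold lower and Hsp90aa1 1.57-fold and Ier3 1.87-fold higher. With TMM factors the medians of STAT5 targets, migration receptors and immediate early genes lay above 0, at 0.039, 0.040 and 0.041, and with DESeq2's factors so did alarmin receptors, at 0.0021. Medians in female-typed cells were -0.09 for alarmin receptors, -0.13 for transcription factors, 0.05 for checkpoint receptors, 0.08 for STAT5 targets, -0.07 for migration receptors and -0.0047 for eicosanoids, at percentiles of 0.05, 0, 65.5, 88.1, 0.71 and 25.6. There they were -0.14 for antigen presentation, -0.10 for the NF-kB response, 0.09 for interferon and -0.25 for immediate early genes, at percentiles of 0.02, 0.05, 95.1 and 0.

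Neuropeptide and neurotransmitter receptors were lower as a list, from few measured genes. The median over 6 measured genes was -0.31 at the 0.06 percentile, and 0.059 in female-typed cells at the 71.5 percentile. Of 5 genes tested, Adrb2 was lower and 4 were within the size rule. Nmbr (ENSMUSG00000019865, chromosome 10, 14705591 to 14770850, mm10), the receptor of neuromedin B, had 0 UMIs in every barcode of both libraries. Over ILC2-like cells the floor of 3 UMIs is 0.0831 CPM in control and 0.0497 CPM in basophil-depleted cells, and the exact interval allows up to 0.124% and 0.0880% of cells with a UMI. These limits hold only if the annotated 3' end of Nmbr is the one its transcripts use, which could not be checked from counts. Nmur1 (chromosome 1, 86386303 to 86426228), the receptor through which neuromedin U activates ILC2s, stood at 6.57 CPM in control and 4.13 CPM in basophil-depleted cells, 1.59-fold lower (1.33 to 1.91), and 1.73-fold lower in female-typed cells (1.22 to 2.52). It lay under the 20 CPM of the size rule. Nmur1 was detected in 1.45% (1.05 to 1.94%) and 1.15% (0.846 to 1.52%) of thinned ILC2-like cells, in 7.23% and 5.61% without thinning, and in 0 of 149 and 0 of 189 T cell-like cells, which allow up to 2.45% and 1.93% by the exact interval. Adrb2, the beta-2 adrenergic receptor, was 1.73-fold lower (1.56 to 1.92) and 1.31-fold lower in female-typed cells (1.10 to 1.57). Its thinned shares, 4.13 and 2.89%, lay below the 6.04 and 3.70% of T cell-like cells. Vipr2, a receptor of vasoactive intestinal peptide, stood at 60.4 and 46.9 CPM, and at 60.2 and 65.8 CPM in female-typed cells. The CGRP receptor gene Calcrl stood at 46.8 and 44.5 CPM, its partners Ramp1 at 532 and 583 CPM and Ramp3 at 44.2 and 36.6 CPM.

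Markers of basophils or mast cells, eosinophils, neutrophils, B cells, erythroid, epithelial, endothelial and stromal cells were each at 50.8 CPM or less in both libraries, while those of T cells were not. Over called cells the summed basophil or mast cell markers stood at 24.4 and 27.9 CPM, those of eosinophils at 2.10 and 1.40, of neutrophils at 7.67 and 3.36, of B or plasma cells at 47.1 and 50.8, and of erythroid cells at 14.2 and 37.9 CPM. Mcpt8, the basophil protease, had 0 UMIs in control cells and 138 in basophil-depleted cells, of which 137 lay in 1 cell, so the gate leaves basophil depletion itself unmeasured. Epithelial markers stood at 40.0 and 31.9 CPM, endothelial at 29.8 and 23.6, and stromal at 2.28 and 1.48 CPM. Monocyte or macrophage markers stood at 399 and 426 CPM, of which Ccr2, also present in ILC2s, gave 321 and 352, and dendritic cell markers at 441 and 492 CPM, of which Cst3 gave 218 and 259. T cell markers stood at 1161 and 1186 CPM, gamma-delta T cell markers at 238 and 215, NK or ILC1 markers at 512 and 359.6, and ILC3 markers at 711 and 568 CPM, beside 3654 and 3528 CPM for ILC2 markers. Of the T cell sum, Trbc2 gave 540 and 532 CPM. Over ILC2-like cells alone the sums were 1041 and 1070 CPM for T cell markers and 220 and 200 for gamma-delta T cell markers. They were 249 and 230 CPM for NK or ILC1 markers and 636 and 518 for ILC3 markers. The T cell, gamma-delta T cell and ILC3 sums therefore do not measure such cells in the sort.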

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

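All tests in this part were chosen after the result was seen. Barcodes of more than 150 and fewer than 500 UMIs lie outside the called cells. Only the free RNA profile of fuller barcodes used them, in an alternative and in the limit on free RNA given further below. In the control library these barcodes held the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at a summed 42.4 CPM, above the 1.79 CPM of a floor of 3 UMIs, while called control cells held 0.196 CPM. Male cells in the control library would give called cells at least the level of those barcodes, and their 0.196 CPM argues against that. Barcode indices exchanged between the libraries may be the source: all 71 of those Y-linked UMIs lay at barcodes with 500 or more UMIs in the basophil-depleted library, as did 31.0% of those control barcodes (2043 of 6587) and 0.139% of the barcode list. At barcodes of basophil-depleted cells the control library held 1.34% as many UMIs as the basophil-depleted library, and 1.63% in the other direction. The free RNA profile of fuller barcodes may therefore hold some UMIs of the other library. A biological explanation other than male cells was not tested.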

How the results depend on the processing

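The female-typed cells, the cells without the 5% highest doublet scores, the cells outside clusters 0 and 7, the female-typed cells outside cluster 7 or at other thinning depths, and the free RNA profile of fuller barcodes were chosen after the data were seen, and the other alternatives before. With 1 sample per group, the spread between mice and pools is unmeasured. No interval covers that spread or the difference in sex between the libraries, at any expression level. Depth sets the counting intervals alone, and by these, genes under about 20 CPM and shares near 1% are the least certain. No paired analysis was possible because each group holds a single sample. The cause of each move below was not tested, except where fewer genes or cells follow from the setting.

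Of 44 named genes past the size rule, all 44 kept their direction under 14 of the 15 alternatives that rescored them. In female-typed cells 7 turned and 10 were still at 1.5-fold. Eif2s3y and Ddx3y had no direction there, since the typing leaves out cells with Y-linked UMIs. Those that turned in female-typed cells had log2 ratios of 0.12 (Pik3ip1), -0.059 (Il13), -0.58 (Ier3), -0.19 (Dgat2), -0.019 (Rrm2), 0.064 (Ccr9) and -0.16 (Fabp5). Of lists outside the central 95% of random lists, those that turned there had medians of 0.059 (neuropeptide receptors), -0.32 (secreted effectors), -0.10 (proliferation), -0.0071 (glycolysis), -0.13 (lipids), 0.043 (ribosomal proteins) and -0.012 (amino acids). Ribosomal proteins also turned to 0.015 with TMM factors and 0.024 with DESeq2's. Of the other lists with a counting interval that excluded 0, medians turned to -0.10 (NF-kB) and -0.0047 (eicosanoids) in female-typed cells, and to -0.049 (NF-kB), -0.049 (checkpoint receptors) and -0.022 (interferon) at most 5% mitochondrial UMIs. Interferon also turned to -0.026 over all called cells, and alarmin receptors to 0.0021 with DESeq2's factors. Mitochondrial transcripts turned to 0.031 with TMM factors, 0.041 with DESeq2's, 0.0028 outside the cycling class, 6.7e-05 with cells weighted equally and 0.014 with free RNA removed by the profile of the emptiest barcodes. The STAT5, migration, antigen presentation and immediate early lists, whose intervals held 0, took both signs.

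The 67 genes higher in the basophil-depleted library became 109 at most 5% mitochondrial UMIs, 10 in female-typed cells, 717 with no CPM minimum, 17 at 100 CPM or more and 7 at 2-fold. The 58 lower genes became 89 without clusters 0 and 7, 1418 with no CPM minimum, 12 at 100 CPM or more and 6 at 2-fold. The secreted effector median of 0.16 was 0.21 with TMM factors, 0.22 with DESeq2's, 0.26 outside the cycling class, 0.35 with cells weighted equally, 0.085 at most 5% mitochondrial UMIs and 0.22 without clusters 0 and 7. The proliferation median of 0.50 was 0.55 with TMM factors, 0.56 with DESeq2's, 0.55 over all called cells, 0.60 outside the cycling class, 0.60 with cells weighted equally and 0.37 without clusters 0 and 7.

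Shares below are given with control first. Cycling cells were 4.94 and 8.62% thinned to 1000 UMIs, 8.44 and 14.3% at 3000, 9.48 and 16.7% with 2 genes needed and 5.28 and 8.21% with 5, and 6.03% among basophil-depleted female-typed cells. Female-typed cycling cells were 4.99 and 3.98% thinned to 1000 UMIs, 8.47 and 7.96% at 3000, and turned to 16.1 and 20.03% unthinned. ILC2-like cells were 81.7 and 85.5% at resolution 2, 79.8 and 88.0% with a minimum of 1000 UMIs, and 79.6 and 85.1% with 3000. Nmur1 was detected in 0.639 and 0.334% thinned to 1000 UMIs and in 7.23 and 5.61% unthinned, and in 1.92 and 1.65% at 3000.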

Other observations

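The tests of transcript GC content and length were planned before their results were seen, and the other tests in this part were chosen after. Female-typed ILC2-like cells, compared between libraries, showed a pattern of their own; its genes, chosen after their values were seen, were mostly lower in the basophil-depleted library. Gzma, a granzyme, was 3.30-fold lower there (2.84 to 3.85), the chemokine genes Cxcl10 2.83-fold (2.34 to 3.45) and Cxcl3 2.02-fold (1.78 to 2.30), and the MHC class II genes H2-Eb1 1.72-fold (1.58 to 1.87) and H2-Ab1 1.54-fold (1.42 to 1.68). Nr4a3, induced by receptor signalling, was 1.53-fold lower and Atf3, a stress-response factor, 1.54-fold. Gzma, H2-Eb1 and H2-Ab1 are among the top 10 genes of cluster 7, which held 10.8% of female-typed control ILC2-like cells (315 of 2905) and 5.65% of female-typed basophil-depleted ones (44 of 779). Without that cluster Gzma was 2.61-fold lower, Cxcl10 2.27-fold, Cxcl3 1.87-fold, H2-Eb1 1.38-fold, H2-Ab1 1.42-fold, Nr4a3 1.46-fold and Atf3 1.56-fold, and Mid1 was 2.89-fold, Tmem158 2.12-fold and Nrgn 1.62-fold higher. Whether the smaller ratios follow the share of that cluster or expression within it was not separated. Over all ILC2-like cells, Cxcl10 and H2-Ab1 both had log2 ratios of 0.23, above 0. The immediate early list had a median of -0.25 in female-typed cells and the antigen presentation list -0.14. Higher genes there included Mid1 at 2.79-fold (2.32 to 3.34), Tmem158 at 2.2-fold (1.88 to 2.56) and Nrgn at 1.71-fold (1.62 to 1.80). The female-typed cells of the basophil-depleted library numbered 779, and how many mice gave them is not known.

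The unnamed Ccr10 cluster held 9.53% of female-typed control cells (8.57 to 10.6%) and 1.95% of female-typed basophil-depleted cells (17 of 870 cells, 1.14 to 3.11%). Its cells carried Il7r at 1326 and 1051 CPM, Rora at 806 and 887 CPM, Il18r1 at 466 and 414 CPM, and Klrg1 at 24.4 and 26.5 CPM. Il13 stood at 69.4 and 128 CPM in them.

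Proliferation genes stood higher in the basophil-depleted library over all ILC2-like cells (median log2 ratio 0.50). The values argue against a different UMI minimum for cells in the libraries as the cause, since a minimum of 1000 UMIs in both left the median at 0.48. In female-typed cells the median was -0.10. Within the basophil-depleted library it was 0.65 in male-typed over female-typed cells, so male cells may carry the difference. However, without thinning the cycling share of female-typed cells was 16.1 and 20.03%, and the typing left out basophil-depleted cells that were cycling more often. Doublets stay open, since leaving out the 5% highest doublet scores (median 0.49) used a caller that has not worked. In the basophil-depleted library 105 ILC2-like cells had 3 or more Xist or Tsix UMIs and a Y-linked UMI, 51 of them with 2 or more Y-linked UMIs. They may include doublets of male and female cells, or cells with free RNA, which was not tested. Basophil depletion acting in male mice alone also stays open and untested, since no control ILC2-like cell was shown to be male: the 11 without Xist or Tsix UMIs held 0 Y-linked UMIs.

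A set of 14 genes, found after the values were seen, was past the size rule against control in both female-typed and male-typed cells: Il2, Gstp1, Gm42047, Gm11808, Uba52, Lgals3, Impact, Bcl2a1b, Ccdc85b, Grcc10 and Klf10 lower, and Alox5, Stc2 and Hba-a1 higher. Taking out the trend over 20 bins of transcript GC content left 14 of the 14 at 1.5-fold in female-typed cells, and so did 20 bins of transcript length (14 of 14). The bin medians taken out were small, from -0.00026 to 0.070 for GC content and from -0.033 to 0.096 for length on the log2 scale. That argues against a trend over all genes with GC content or length as the whole cause. The 14 had been picked for passing 1.5-fold in these cells, and were shorter (median 1537.5 bases against 3215 for tested genes). An effect of length on these genes alone was not tested. The most free RNA that Il13 in T cell-like cells allows brings at most 86.2% of any of the 14 differences, which argues against free RNA as the whole cause. Cells outside the ILC2-like class were also compared, with each class compared with itself and the sexes pooled. There 4 of the 14 (Il2, Gm11808, Lgals3 and Bcl2a1b) had counting intervals apart from those in all ILC2-like cells. The upper end of the central 95% of draws with equal ratios was 2. Counts of Gm11808 and Bcl2a1b are uncertain because near-identical copies share their sequence, and the draws held counting error only. Whether the difference was of equal size in every cell class is therefore not settled. All 14 had the same sign outside the class, with a median signed log2 ratio of 0.57 against 0.91 in the class. Only 9 of the 14 had a counting interval outside the class that excluded 1, so the sign of the others is uncertain. A difference of equal or unequal size shared by the cell classes of a library, such as strain or handling, could give these values. Free RNA of ILC2-like cells in the other classes could also give the same signs, and this was not tested. An effect of basophil depletion on all sorted classes stays open and untested.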
